A study of Mus musculus with 12 samples.

How the data were processed

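The series measured messenger RNA by bulk RNA sequencing in 12 mouse lung tumour samples, 6 from KP animals and 6 from KPP animals. Both genotypes carry a Kras allele and a Trp53 allele that Cre recombinase alters, and KPP animals carry in addition a Cre-activated Plk1 insert in the Rosa26 locus. Tumours were taken 12 weeks after an adenovirus carrying Cre had been delivered. Per the labels' protocols, polyadenylated RNA was selected with poly-T beads, fragmented, and copied from random hexamers. Whether the libraries kept strand information is not given in the sources used here.

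Per the submitters' processing notes, CASAVA, STAR 2.5 and HTSeq 0.6.1 were used on the mouse build mm10. The annotation is not given in the sources used here. The deposited table held read counts per gene for each sample, per the file headers, as whole numbers with no normalization. The authors also deposited FPKM values, and in each of the 12 libraries the FPKM denominator equalled the sum of the count column. Per the file headers, the authors' own comparison gave a log2 fold change for each gene. It also gave p-values and adjusted p-values, per the file headers, and the tool behind them is not given in the sources used here. The authors' gene length column, in bases as deposited, is another quantity that was used only to check the FPKM values. The table calls the second group KPPI where the sample titles say KPP, and the replicate numbers 1 to 6 were matched on that reading. Of the table's rows, 24294 held a gene and 10981 were blank in every column and were left out. A spreadsheet had turned 25 gene symbols into dates, and those genes were kept by their identifiers. A further 36 columns of per-sample values, such as repeated FPKM and the authors' normalized values, were not used.

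Of the gene identifiers, 23996 were found in the GENCODE M21 annotation of the same build (GRCm38), and 95.0% of those lay on the same chromosome with a start within 1000 bases. Coordinates are those of the deposited table. Library totals ranged from 17700486 to 27523914 counts, and they were summed over genes only.

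Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 15174. TMM factors, robust quasi-likelihood fits and the Benjamini-Hochberg adjustment followed, with a threshold of 0.05. The standard error of a log2 fold change was computed from its F statistic. CPM values used TMM-scaled library sizes, and log2 CPM used a prior count of 2. The labels do not say whether each sample came from a separate animal, so the p-values measure the spread between these samples. No batch, sex or day was given in the labels, and no covariate was used. Single values were compared by exact 2-sided permutation tests over all 924 assignments of the 12 samples, for which the smallest p is 0.00216.

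The 34 gene lists, with 551 symbols of which 546 were found in the table, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The rule named Plk1, Ret, Kras and Trp53 always. It then named up to 12 protein-coding genes per direction with an adjusted p under 0.05 and a mean of at least 5 CPM in 1 group, and up to 4 members of each list with the smallest p. Genes outside this rule are said to have been chosen after their values were seen.

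The fit was tested on simulated counts for the comparison of KPP with KP, drawn for 15174 genes from the real means, library sizes and dispersions. Of 67 genes changed by a log2 value of 1, 16.4% were recovered. The share was 73.1% of 67 genes at a log2 value of 2 and 98.5% of 66 genes at a log2 value of 4. Among 134 genes called in these simulated counts, 4 had not been changed. When fewer genes change, the adjustment asks for a smaller unadjusted p. The real fit called 1 gene, so the shares recovered may overstate what it could detect. A simulated list moved by a log2 value of 1 gave a camera p of 7.36e-24, and one left alone gave 0.897. The genes were drawn independently of each other, so these values cannot show how camera acts on lists whose members are correlated.

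Alternatives were RLE and upper-quartile factors, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, the replicate number as a block, leaving out genes above 1% of a library, a Y-linked score as a covariate, and each library left out in turn. After the data had been seen, fits without KPP 1 and KPP 2, with these libraries summed as 1 sample, and without KPP 3 and KP 6 were added. Counts of calls were compared over 100 splits of the 12 samples into groups of 6, the real split included, drawn with a fixed seed from the possible splits. Permutations and plots used Python with numpy, scipy and matplotlib. Reads of genes with close paralogs, or of genes that overlap another gene, may have been divided in the authors' counting. The counts also cannot separate the Plk1 insert from the endogenous gene.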

Results

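Gene expression was measured in 12 mouse lung tumour samples taken 12 weeks after Cre delivery. The KP group (6 samples) had an activatable mutant Kras allele and floxed Trp53, a widely used model of lung adenocarcinoma. The KPP group (6 samples) had in addition a Cre-activated Plk1 insert in Rosa26. Plk1 encodes a kinase that drives entry into and passage through mitosis. The KPP libraries held 17700486 to 27523914 counts and the KP libraries 18151343 to 21236707. The comparison asked which genes differ when Plk1 is overexpressed, and the series title names the receptor tyrosine kinase gene Ret as a gene of interest.

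Plk1 (ENSMUSG00000030867, mm10 chromosome 7, 122159437 to 122169875) was higher in all 6 KPP libraries than in any KP library. Its level was 345 ± 167 CPM in KPP (SD, n = 6) and 18.6 ± 6.67 CPM in KP (SD, n = 6). The log2 fold change was 4.21 ± 0.42 (SE), with an adjusted p of 0.00212 in edgeR's quasi-likelihood test. An exact 2-sided permutation test of log2 CPM gave p = 0.00216, the smallest it can give, and 0.0108 after adjustment over 5 measures. Plk1 was the only gene of 15174 past the threshold. The lowest KPP count of Plk1 was 1725, in KPP 3, and the highest KP count was 551, in KP 2. No other member of the Polo-like kinase list, which had 5 genes tested, passed the threshold, and the other members' fitted values were below 0.

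**Figure D1:**
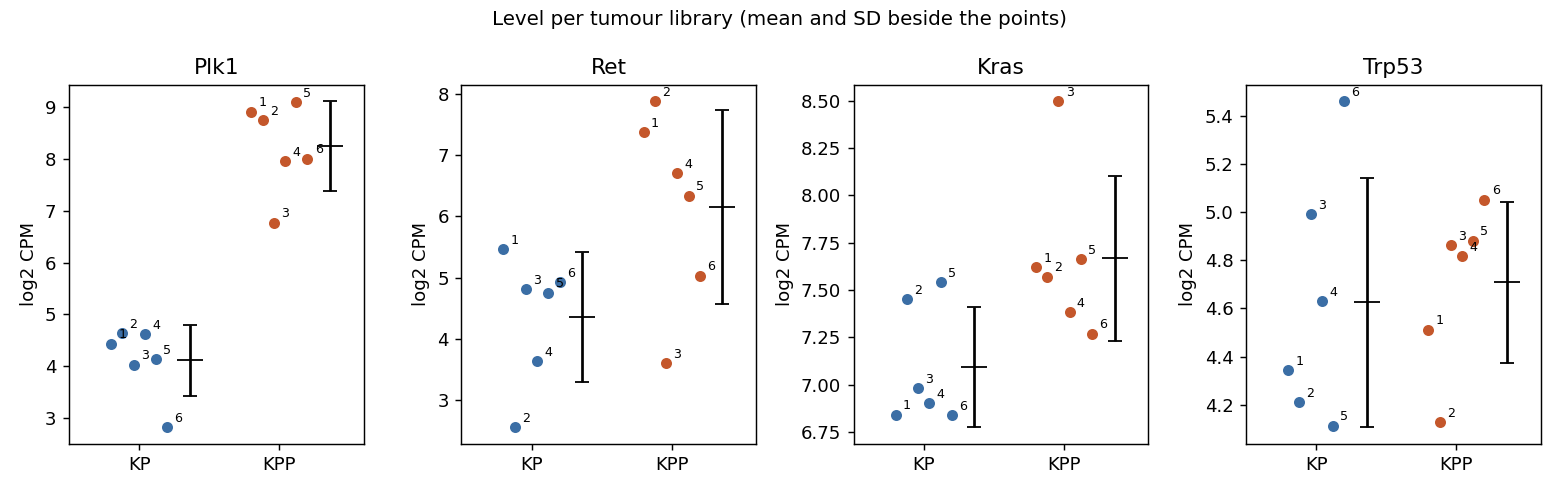
Level of Plk1, Ret, Kras and Trp53 in log2 CPM (vertical axes, each with its own range) in 6 KP and 6 KPP tumour libraries. Points are libraries with their replicate number, and the bar beside each group is the mean and SD. Plk1 was higher in all 6 KPP libraries, whereas Ret in KPP 3 and KPP 6 lay within the KP range.

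Ret (ENSMUSG00000030110, mm10 chromosome 6, 118151748 to 118197744), which encodes a receptor tyrosine kinase for GDNF family ligands, had a mean of 105 ± 83.9 CPM in KPP and 24.6 ± 13.7 CPM in KP (SD, n = 6 each). Of the 6 KPP libraries 4 lay above all KP libraries. The log2 fold change was 2.10 ± 0.63 (SE) with an adjusted p of 0.391 in edgeR, so Ret did not pass the threshold over all genes. DESeq2 gave a log2 fold change of 2.09 and an adjusted p of 0.0403. In the authors' deposited table, which is not independent of these counts, Ret had a log2 fold change of 1.43 and an adjusted p of 0.0498. The unadjusted p of Ret was 0.000398 there and 0.000373 with the DESeq2 Wald test. The deposited fold change was thus smaller at nearly the same p, and 1.43 is not a like estimate to 2.09. The exact 2-sided permutation test on log2 CPM gave p = 0.0455, or 0.0758 after adjustment over 5 measures. The libraries KPP 1 and KPP 2 had Xist levels of 2686 and 3048 CPM and no Ddx3y counts, whereas Ddx3y was detected in the other 10 libraries. Without KPP 1 and KPP 2, which are KPP libraries only, the Ret log2 fold change was 1.23 ± 0.60 (SE), with an edgeR adjusted p of 0.608, and with the Y-linked score of each library as a covariate it was 1.27 (edgeR adjusted p 0.511). With the 8-gene list of RET, its ligands and co-receptors the camera adjusted p was 0.470, and 1 member, Ret, passed when adjusted over the list alone.

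Kras (ENSMUSG00000030265, chromosome 6, 145216699 to 145250239) had a log2 fold change of 0.61 ± 0.22 (SE), with 212 ± 75.5 CPM in KPP and 139 ± 32.4 CPM in KP, and an edgeR adjusted p of 0.433. Without KPP 3, where Kras was at 361 CPM, the log2 fold change was 0.39. The exact permutation test on its log2 CPM gave p = 0.0216, or 0.0541 after adjustment over 5 measures. Trp53 had a mean log2 CPM of 4.71 ± 0.33 in KPP (SD, n = 6) and 4.62 ± 0.52 in KP. Its log2 fold change was 0.03, which is within its standard error of 0.25, and its sign turned with the scaling (−0.016 with upper-quartile factors).

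Over all genes, edgeR called 1 gene (1 higher, 0 lower). At an unadjusted p under 0.05 there were 1500 genes, 767 higher and 733 lower, and 12 of 100 splits of the 12 samples gave as many. The biological coefficient of variation was 0.493, and the simulated counts recovered 16.4% of genes changed by a log2 value of 1. That share may be too high for the real fit. The simulation called 134 genes, and the adjusted threshold is stricter when fewer genes change. The values of the 2 groups did not overlap for 88 genes, or 0.580% of those tested, where chance gives 0.216% on average. This share was not computed for other splits of the samples, so chance cannot be excluded for it. DESeq2 called 188 genes, 46 higher and 142 lower, of which 149 were tested by edgeR and all 149 had the same sign and an unadjusted p under 0.05 there. The authors' deposited table called 134 genes, 37 higher and 97 lower, all 134 of them among the DESeq2 calls. Both rest on the same counts. For Kras the deposited unadjusted p was 0.01644 and that of the DESeq2 Wald test 0.01643. For Trp53 they were 0.92063 and 0.92062. The overlap is thus not independent evidence. The 2 comparisons were not the same for every gene. For Agr2 the deposited unadjusted p was 0.0179 and that of the DESeq2 Wald test 5.76e-05. Across genes, Pearson's r between their log2 fold changes was 0.713. Without KP 6 edgeR called 4 genes, adding Gm5801, Atp8a2 and P4ha2. Without KPP 6 it called 2, adding Slc5a5. Those 4 added genes were chosen after their values were seen.

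Several genes with the smallest p, chosen after their values were seen, had groups that did not overlap. Aldh2, a mitochondrial aldehyde dehydrogenase, had 784 ± 67.7 CPM in KPP against 423 ± 41.5 CPM in KP and a log2 fold change of 0.89 ± 0.14 (SE), with an edgeR adjusted p of 0.146. Il18, a cytokine of the interleukin 1 family, had 4.36 ± 1.57 CPM against 14.4 ± 3.64 CPM and a log2 fold change of −1.72 ± 0.30 (edgeR adjusted p 0.263). Smim3 and Ube2a, the latter a ubiquitin-conjugating enzyme gene, had log2 fold changes of 1.21 and 1.22. Tsen54, a tRNA splicing subunit, Aldoc, a glycolytic aldolase, and Mlxipl, a glucose-responsive transcription factor, had −1.03, −1.04 and −2.28. None of these genes passed the edgeR threshold, and each was called by DESeq2.

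Of 34 gene lists, camera with the preset correlation called 10, 5 higher and 5 lower in KPP. The number of lists called in each direction depended on single libraries. None of these 10 lists changed direction in any alternative that tested lists. Higher and lower calls numbered 1 and 5 without KP 5, and 2 and 8 without KPP 6. They numbered 2 and 4 without KP 1, 2 and 3 without KP 4, and 3 and 4 without KPP 5 or KP 2. The counts were 4 and 3 without KPP 2, and 6 and 3 without KP 6. They were 7 and 4 with the Y-linked covariate, 9 and 4 without KPP 1 and KPP 2, and 1 and 3 at a mean of at least 5 CPM. None held with an estimated correlation, where the smallest adjusted p was 0.407, and none with fry, where it was 0.194. MHC class II genes, which present antigen to helper T cells, were higher as a list: 9 of 9 tested members had positive values, 0 passed over all genes and 0 adjusted over the list alone. The camera adjusted p was 0.00176, and the adjusted p was 0.842 with an estimated correlation. H2-DMb1 had 170 ± 61.4 CPM in KPP against 112 ± 17.8 CPM in KP, a log2 fold change of 0.61 ± 0.23 (SE). H2-Ab1 had 718 ± 304 CPM against 425 ± 138 CPM, a log2 fold change of 0.76 ± 0.28. This list kept its call in each of the 12 fits that left out a library, with adjusted p values up to 0.0149.

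The mesenchymal and invasion list (19 of 19 tested members positive) and the fibroblast and pericyte list (14 of 20) both had a camera adjusted p of 0.0259, and an adjusted p of 0.842 with an estimated correlation. S100a4, a calcium-binding protein gene linked to motility, had a log2 fold change of 1.78 ± 0.51 (SE), and Vim, an intermediate filament gene, 1.54 ± 0.70. Pdgfrb, a pericyte receptor gene, had 0.89 ± 0.35. Single libraries carried much of these values: without KPP 3 the log2 fold change of S100a4 was 0.91 and that of Vim 0.39, and without KPP 6 that of Pdgfrb was 0.47. Over all genes none of these passed in edgeR, and 0 members of either list passed when adjusted over the list alone. The means of the mesenchymal list were 6.48 in both KPP 3 and KPP 6 and 3.27 to 4.16 in the other KPP libraries (log2 CPM). The KP libraries were at 3.45 to 5.44 with a mean of 4.21, so those other KPP libraries all lay below the KP mean. Its call was lost without KPP 3, KPP 6, KP 1 or KP 5, with adjusted p values of 0.0556 to 0.446, and that of the fibroblast list without KPP 3, KPP 6, KP 1, KP 4 or KP 5, with values of 0.0519 to 0.477. At a mean of at least 5 CPM both calls were lost as well (0.0917 and 0.0997), and the mesenchymal call also without KPP 3 and KP 6 (0.287).

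The endothelial list had 18 of 20 members with positive values and a camera adjusted p of 0.0259 (0.856 with an estimated correlation). Its member with the smallest p went the other way: Car4, a carbonic anhydrase of lung capillary cells, had 18.5 ± 7.45 CPM in KPP against 51.9 ± 26.1 CPM in KP, a log2 fold change of −1.49 ± 0.35 (SE), and was the 1 member that passed when adjusted over the list alone. Aplnr and Cldn5 had log2 fold changes of 0.52 ± 0.35 and 0.52 ± 0.37, and without KPP 6 the value of Aplnr was −0.012. Cldn5 was at 0.28 without KPP 5 and 0.91 without KP 6. The red blood cell list (3 of 3 tested members positive) had a camera adjusted p of 0.0259, and 0.771 with an estimated correlation. Hbb-bs, a haemoglobin gene, had a log2 fold change of 1.07 ± 0.40. The endothelial call was lost in 6 of 12 fits that left out a library (KPP 5, KPP 6, KP 1, KP 2, KP 4 or KP 5; adjusted p 0.0501 to 0.270), and the red blood cell call in 5 (KPP 2, KPP 5, KP 2, KP 4 or KP 5; 0.0623 to 0.0951). Both were lost at a mean of at least 5 CPM (0.0670 and 0.183), and the red blood cell call also with the Y-linked covariate (0.0849) and without KPP 1 and KPP 2 (0.0878).

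**Figure D2:**
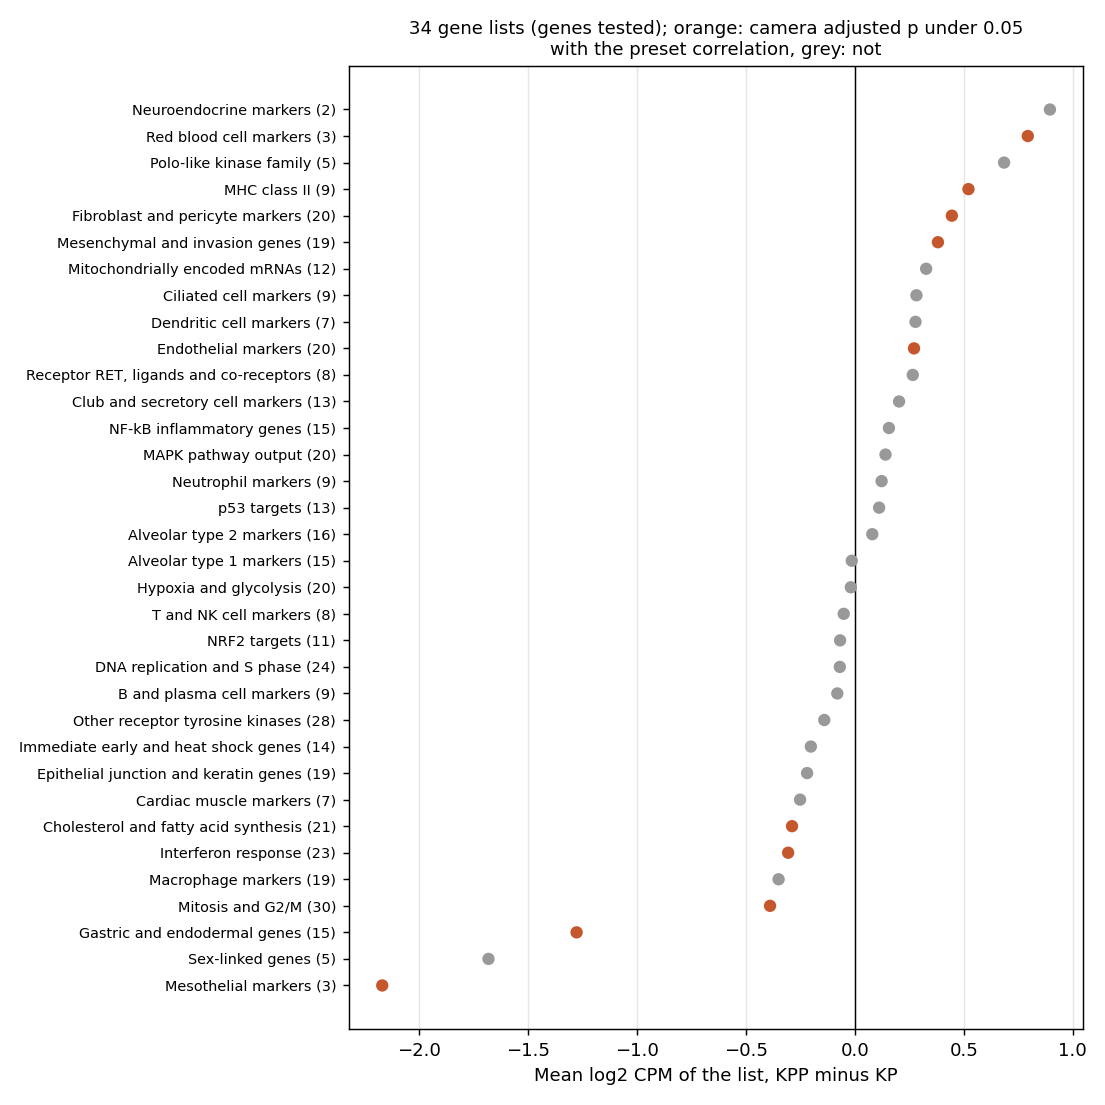
Difference of the group means of each list's mean log2 CPM (horizontal axis, KPP minus KP) for 34 gene lists, with the number of tested genes in brackets. Orange points had a camera adjusted p under 0.05 with the preset correlation, and none held with an estimated correlation. The mesothelial list, at 1.13 in KPP and 3.30 in KP, lay farthest to the left.

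Genes of mitosis and the G2/M phase were lower as a list in KPP: 29 of 30 members had negative values, with a camera adjusted p of 0.00176 (0.842 with an estimated correlation). Over all genes 0 members passed, and 0 when adjusted over the list alone. The kinesin gene Kif11 had a log2 fold change of −0.99 ± 0.34 (SE), the proliferation marker Mki67 −0.88 ± 0.33, Kif23 −0.99 ± 0.42 and Cdc20, an activator of the anaphase-promoting complex, −0.56 ± 0.24. Kif23 was at −0.60 without KP 2 and −1.21 without KP 6. The call was lost without KPP 5, with an adjusted p of 0.0571. The list of DNA replication genes had a camera adjusted p of 0.638.

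Gastric and endodermal genes were lower as a list (13 of 15 tested members negative; camera adjusted p 0.0108, and 0.842 with an estimated correlation), and 3 members passed when adjusted over the list alone. Tff3 and Agr2, secretory epithelial genes, averaged 0.835 ± 0.976 and 1.02 ± 1.13 CPM in KPP against 66.7 ± 110 and 74.1 ± 122 CPM in KP. The SDs in KP exceeded the means, and without KP 4 the KP means were 22.7 and 28.4 CPM. In KPP the Tff3 mean was 0.550 CPM without KPP 2 and the Agr2 mean 0.592 CPM without KPP 6. Gkn1, a gastric mucosal gene, had a log2 fold change of −2.66 ± 0.82 and Vil1, a microvillus gene, −1.75 ± 0.70. The call was lost without KPP 3, with an adjusted p of 0.0714.

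**Figure D3:**
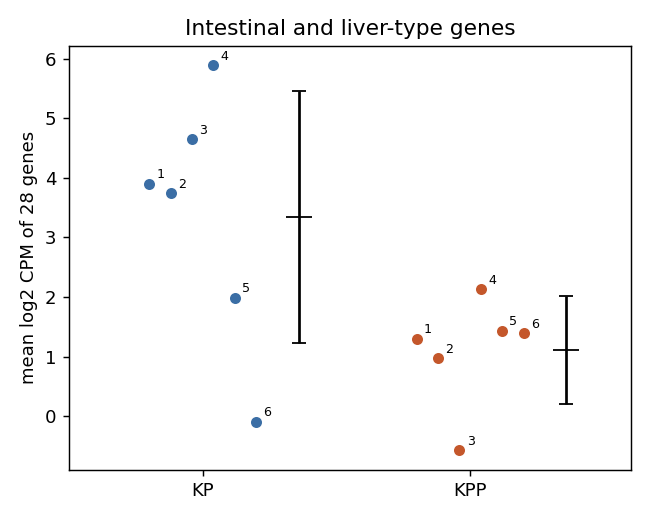
Mean log2 CPM (vertical axis) of 28 intestinal and liver-type genes, chosen after their values were seen, in 6 KP and 6 KPP tumour libraries. Points are libraries with their replicate number, and the bar beside each group is the mean and SD. KP 3 and KP 4 were at 4.65 and 5.89, and the KPP libraries at −0.57 to 2.13.

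The mesothelial list was lower in KPP with 3 tested members (camera adjusted p 0.0108; 0.407 with an estimated correlation), and its members moved apart. Upk3b and Upk1b had log2 fold changes of −3.33 ± 1.07 and −2.80 ± 0.98 (SE), and both passed when adjusted over the list alone, whereas Msln, the mesothelin gene, had 0.79 ± 0.92 and turned to −1.08 without KPP 3. Upk3b was at −1.79 without KP 6 and −4.07 without KPP 6, and Upk1b at −4.15 without KPP 4. The call was also lost with the Y-linked covariate, with an adjusted p of 0.0503. Cholesterol and fatty acid synthesis genes (18 of 21 negative) had a camera adjusted p of 0.0259, and interferon response genes (17 of 23 negative) one of 0.0441. Both had an adjusted p of 0.842 with an estimated correlation. Fdft1, a squalene synthesis gene, had a log2 fold change of −0.41 ± 0.19, Oas1a, an antiviral sensor gene, −1.72 ± 0.49, and Cd274, which encodes the immune checkpoint ligand PD-L1, −1.41 ± 0.51 (−0.93 without KP 4 and −2.02 without KPP 6). The cholesterol call was lost in 5 of 12 fits that left out a library (KPP 2, KPP 4, KP 2, KP 4 or KP 6; adjusted p 0.0590 to 0.240), and the interferon call in 6 (KPP 1, KPP 2, KPP 3, KP 1, KP 4 or KP 6; 0.0918 to 0.539). Over all alternatives the interferon call was lost in 15 of 24, among them upper-quartile factors (0.0665), no low-count filter (0.0558), a mean of at least 5 CPM (0.187), the Y-linked covariate (0.451), and KPP 1 and KPP 2 left out (0.348) or summed (0.128). The fit without KPP 3 and KP 6 ended both the interferon call (0.768) and the cholesterol call (0.0978), and the fit without KPP 1 and KPP 2 the cholesterol call (0.0587).

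The other 24 lists did not pass, with camera adjusted p values from 0.0950 for macrophage markers to 0.967 for B and plasma cell markers. Within the macrophage list, 3 members passed when adjusted over the list alone and moved apart: Chil3 and Gpnmb had log2 fold changes of −1.51 ± 0.38 and −2.15 ± 0.60 (SE), and Mafb, a monocyte and macrophage transcription factor gene, 0.88 ± 0.25. Gpnmb was at −1.38 without KP 4 and −2.45 without KPP 5. MAPK pathway output genes, read out downstream of Kras, had 17 of 20 members with positive values and a camera adjusted p of 0.369, with Emp1 at 1.23 ± 0.58 and Dusp6 at −0.42 ± 0.24 (Emp1 0.64 without KPP 3 and 1.58 without KP 2; Dusp6 −0.21 without KP 2). Alveolar type 2 markers, the surfactant-producing cell type, had an adjusted p of 0.721, and p53 targets one of 0.539. For the other receptor tyrosine kinases it was 0.692, with Erbb2 at −0.38 ± 0.14. The median of member log2 fold changes and the camera direction had opposite signs for 5 lists: the Polo-like kinases, the other receptor tyrosine kinases, the cardiac, alveolar type 1, and hypoxia and glycolysis lists. The mean and the camera direction had opposite signs for the sex-linked, other receptor tyrosine kinase, cardiac, T and NK cell, NRF2, alveolar type 1, and hypoxia and glycolysis lists.

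The share of counts from mitochondrially encoded genes was 3.56% ± 2.94 in KPP and 3.22% ± 2.45 in KP (SD, n = 6 each; exact 2-sided permutation p = 0.719, 0.742 after adjustment over 5 measures). It was 9.45% in KPP 3 and 7.92% in KP 6, and 1.33% to 3.73% in the other 10 libraries. KPP 3 also had the lowest level of the surfactant gene Sftpc, 5630 CPM, against 8199 CPM or more in the other 11 libraries. Without KPP 3 and KP 6 edgeR called 2 genes, Plk1 and Gm5801, and camera called 10 lists. KPP 1 and KPP 2 were the most alike of the 30 pairs of libraries within groups, with a correlation of 0.981 over log2 CPM against 0.948 for the next pair, and a chi-square of 21.7 per gene against 72.3. Their counts differed by more than counting error, so they were not copies of 1 set of reads, but the labels do not say whether they came from 1 animal or tumour. They entered the fit as 2 samples. With their counts summed as 1 sample the Ret log2 fold change was 1.81, with an edgeR adjusted p of 0.585, and Plk1 remained past the threshold.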

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

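The splits for DESeq2, for lists and for unadjusted p values, the test of Ret without KPP 1 and KPP 2, the test of a linked haplotype, and the test on the KP libraries with the highest intestinal and liver-type levels were chosen after their results had been seen. In a search of 226 groups of 6 values, 27 times a group had a library whose gap to the next was above Dixon's 95% critical value as a share of the range. Chance alone would give about 11.3 if the groups were independent. They share the same libraries, so the excess over this number decides nothing. Gm5801, Atp8a2 and P4ha2 were in the search because edgeR called them without KP 6, so their gaps in KP 6 were to be expected.

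For depth, KPP 4 held 27523914 counts, with a gap of 0.804 of the range to the next KPP library. The mitochondrial share was high in KPP 3 (gap 0.823) and in KP 6 (0.635). KPP 3 was also highest for Kras (0.680), S100a4 (0.657) and Epha4 (0.694), and lowest for Vil1 (0.784), the gastric and endodermal list (0.766) and the epithelial junction and keratin list (0.762). KP 6 was lowest for Plk1 (0.668), Vil1 (0.647) and Atp8a2 (0.654), and highest for Upk3b (0.791), Cldn5 (0.779), Gm5801 (0.768), P4ha2 (0.858) and the endothelial list (0.779). KPP 6 was highest for Cd274 (0.634), S100a9 (0.673), S100a8 (0.723), Aplnr (0.701) and the neutrophil list (0.741), and lowest for Gt(ROSA)26Sor (0.635). KPP 5 was lowest for Cdc20 (0.740), KP 2 highest for Col5a1 (0.768), KP 4 highest for S100a8 (0.666) and KP 5 highest for Pard6g (0.776).

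The first pattern is the higher Ret level in KPP. A gain that raised the chromosome 6 region across KPP by the bound of 1.05, set from the value of Ret, is argued against. The 183 other tested genes within 10 Mb of Ret had a median log2 fold change of 0.063. This lay at percentile 59.4 of 10641 overlapping windows on other chromosomes. Its 95% interval, −0.01 to 0.14, came from resampling genes and not libraries. Smaller gains, or gains in some libraries only, stay open. Over all chromosome 6 genes the median level was 0.20, 0.16, −0.31, 0.12, 0.06 and −0.01 in KPP 1 to KPP 6. The highest were in the KPP libraries with Ret above all KP libraries. In KP, however, KP 2 had the highest level (0.08) and the lowest Ret. A different share of alveolar type 2-like RNA is argued against only as a difference between the group means. That list's mean was 9.995 ± 0.988 in KPP and 9.916 ± 0.666 in KP (log2 CPM, SD). As a covariate it could thus remove little, and with it Ret had a log2 fold change of 1.67 ± 0.38 (SE). Within KPP the list mean and Ret were both lowest in KPP 3 and KPP 6, and within KP in KP 2 and KP 4. KPP 5, highest for the list, was not highest for Ret. A part of this share in the Ret level of single libraries stays open. A haplotype linked to the Rosa26 insert stays open and cannot be told apart from an effect of the insert itself, since a variant in it could act on Ret alone and leave its neighbours as they were. Of the 183 neighbours 16, a share of 0.0874, had an unadjusted edgeR p under 0.05, at percentile 41.0 of the windows, and 1 KPP library lay below the KP median of Ret. Neither value decides it, as all KPP samples carry the insert. Also open is the part played by KPP 1 and KPP 2: without them Ret was at 1.23 ± 0.60 (SE), above the same bound by less than its standard error. An effect of Plk1 on Ret, the relation the title names, may account for the difference, but it was not tested apart from the genotype.

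The second pattern is the set of calls. For edgeR, 4 of 100 splits of the 12 samples gave at least the 1 gene of the real split, with 156 genes in the highest of the other splits. That gene was Plk1, which the insert raises by design, so the count excludes chance for no other gene. For DESeq2, 8 of 100 splits gave as many as the 188 genes of the real split, the highest of the others gave 1465, and chance cannot be excluded for the count. For genes at an unadjusted edgeR p under 0.05, 12 of 100 splits gave as many as 1500 and the highest of the others gave 3269, so chance cannot be excluded there either. For the lists, 40 of 100 splits gave as many as 10 with the preset correlation, the highest of the others gave 17, and chance cannot be excluded. The splits with 156 edgeR calls and with 1465 DESeq2 calls both set KPP 1, KPP 2, KPP 4, KPP 5 and KP 6 with 1 other KP library against the rest, which points to a structure among the samples other than the genotype.

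The third pattern is the negative log2 fold changes of intestinal and liver-type genes in KPP, none of which passed over all genes in edgeR. DESeq2 called some of them, such as Fcgbp, Spink4, Apoa1 and Agr2, but chance could not be excluded for its count of calls. Without KP 3 and KP 4 the median log2 fold change of the 28 genes was −1.58 against −2.55 with all libraries. The 95% interval of the former, −1.86 to −1.04, came from resampling genes and not libraries. These libraries were left out because they had the highest levels of the same genes, and the genes had been chosen after their values were seen, so a smaller median was to be expected and decides nothing. KP 1 and KP 2, at 3.90 and 3.74, also lay above all KPP libraries, which reached at most 2.13, whereas KP 5 and KP 6 did not. A few high KP libraries and a difference between the genotypes cannot be told apart, since both the genes and the libraries were picked by these values.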

How the results depend on the processing

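The fits without KPP 1 and KPP 2, with these summed, and without KPP 3 and KP 6 were chosen after seeing the data. Plk1 kept its direction and its call in every fit run, with log2 fold changes of 4.04 to 4.40 when 1 library was left out. Ret kept its direction in every fit and was past the threshold only with DESeq2 (2.09). Its values were 1.69 to 2.36 when 1 library was left out, 1.27 with the Y-linked covariate, 1.46 with limma-trend on FPKM and 1.23 without KPP 1 and KPP 2. The count of genes, 1 in the edgeR fit reported, was 188 with DESeq2, 1 to 4 when 1 library was left out, and 2 without KPP 3 and KP 6. The count of lists, 10, was 4 with a mean of at least 5 CPM, 0 with an estimated correlation, 0 with fry, and 5 to 12 when 1 library was left out. It fell to 6 without KP 1 or KP 5 and to 5 without KP 4, and was 13 without KPP 1 and KPP 2. The stricter filter leaves fewer list members. An estimated correlation widens the test only where it exceeds the preset 0.01. For the 10 called lists the estimates were 0.0642 (mesothelial) to 0.657 (endothelial), so the preset was below the correlation estimated in these data. The cause of the other changes was not tested.

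Among 75 named genes, 1862 values under an alternative held 1819 with the same direction and side of the threshold, 30 past it that were not before, and 13 with the opposite sign. The latter belonged to 4 genes, none past the threshold. Msln was −0.77 with limma-voom, −0.77 with limma-trend on FPKM, −0.91 with the replicate block, −0.70 without KPP 3 and KP 6, and −1.08 to 1.16 when 1 library was left out. Trp53 was −0.016 with upper-quartile factors and −0.061 to 0.25 when 1 library was left out. Aplnr was −0.012 to 0.65 when 1 library was left out. Sftpc was 0.28 without KPP 3 and KP 6, and −0.53 to 0.064 when 1 library was left out. The cause was not tested. For the 10 called lists, 169 of 239 values kept the call and 70 lost it.

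The replicate numbers did not pair the samples: correlations of deviations between same-numbered libraries were −0.217 to 0.0375, and 0 of 6 KPP libraries matched their own number best. With the replicate number as a block the count of genes was 1, Plk1 had a log2 fold change of 4.15 with an edgeR adjusted p of 0.0429, Ret 1.74, and 11 lists were called.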

Other observations

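The intestinal and liver lists and most single genes in this part were chosen after their values had been seen, and the correlations after the data had been seen, whereas the test on chromosome 6 was set beforehand. Several genes of the intestinal epithelium and of liver type had negative log2 fold changes in KPP. None of them was past the edgeR threshold over all genes (smallest adjusted p 0.361). DESeq2 called Fcgbp (adjusted p 6.79e-05), Spink4 (0.00308), Apoa1 (0.00414) and Agr2 (0.0136), but not Tff3 (0.0516) or Vil1 (0.185). The authors' deposited table called Hpx, Pipox, Muc2, Gpa33, Myo1a and Fabp1, but not Apoa1 or Agr2. Of 14 tested intestinal genes all 14 had negative values, with a median log2 fold change of −2.81, and 13 had an unadjusted edgeR p under 0.05. Fcgbp, a mucus protein gene, averaged 3.14 ± 2.13 CPM in KPP against 270 ± 514 CPM in KP (SD, n = 6 each), and Spink4, a goblet cell gene, 0.347 ± 0.419 against 27.6 ± 47.3 CPM. Without KP 4 the KP means were 61.5 and 8.54 CPM, and the log2 fold change of Fcgbp was −4.26 in place of −6.41. Without KPP 2 the KPP mean of Spink4 was 0.196 CPM. Of 14 tested liver-type genes 13 were negative, with a median of −2.28. Apoa1, an apolipoprotein gene, had a log2 fold change of −5.43 ± 1.30 (SE), −4.07 without KP 4 and −6.09 without KPP 4. Per library, the mean log2 CPM of the 28 genes was 5.89 in KP 4, 4.65 in KP 3, 3.90 in KP 1, 3.74 in KP 2, 1.99 in KP 5 and −0.09 in KP 6, and −0.57 to 2.13 in the KPP libraries.

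Of the genes chosen after their values were seen, Lce3f and Crct1, genes of the cornified skin envelope, and Krt14, a basal keratin gene, had log2 fold changes of −5.10, −4.60 and −3.24 in KPP, from means of 4.67, 6.76 and 16.1 CPM in KP. The values of Lce3f and Crct1 were −4.40 and −3.98 without KP 2, and −5.66 and −5.11 without KPP 4. Pbp2 had 10.4 ± 14.1 CPM in KPP against 0.320 ± 0.285 CPM in KP, and its mean was 4.73 CPM in KPP without KPP 3 and 0.209 CPM in KP without KP 6. Pard6g, a cell polarity gene, had a log2 fold change of 1.66 ± 0.32 (SE). Members of the club cell list went both ways: Scgb3a2, a secretory gene, had a log2 fold change of −3.13 ± 1.31 (SE; −1.98 without KP 4 and −3.76 without KPP 3), and Cckar, Lypd2 and Cbr2 had 2.10 ± 0.73, 2.09 ± 1.18 and 1.12 ± 0.90. When 1 library was left out, Cckar was at 1.73 (KPP 3) to 2.79 (KP 1), Lypd2 at 0.34 (KPP 4) to 2.93 (KP 3) and Cbr2 at 0.59 (KPP 5) to 1.69 (KP 6). So did those of the neutrophil list, with Cd177 at −2.54 ± 0.83 and S100a9, S100a8 and Il1r2 at 1.89 ± 0.70, 1.75 ± 0.71 and 2.10 ± 0.89. The same ranges were −3.11 (KPP 1) to −1.74 (KP 4) for Cd177, 0.56 (KPP 6) to 2.11 (KPP 2) for S100a9, 0.33 (KPP 6) to 2.06 (KP 4) for S100a8 and 1.44 (KPP 6) to 2.46 (KP 2) for Il1r2. None of these passed the edgeR threshold. DESeq2 called Lce3f, Crct1, Krt14, Pbp2, Pard6g and Cd177, but not Scgb3a2, Cckar, Lypd2, Cbr2 or Il1r2. The host transcript of the Rosa26 locus, Gt(ROSA)26Sor (chromosome 6, 113067428 to 113077333), had a log2 fold change of 0.59 ± 0.27 (SE), with 4 of 6 KPP libraries above all KP libraries.

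Within the groups, 4 relations with Plk1 in log2 CPM were computed over 6 libraries each, with exact permutation p values over all pairings. For Ret in KPP Pearson's r was 0.834 (exact p = 0.0375, adjusted 0.0750) and Spearman's rho 0.486 (exact p = 0.356, adjusted 0.356), with r = 0.766 without the 2 libraries farthest from the median of Plk1. In KP the values were r = −0.471 (exact p = 0.339, adjusted 0.339) and rho = −0.657 (exact p = 0.175, adjusted 0.322), and r = −0.434 without 2 libraries. For the mitosis list mean in KP r was 0.963 (exact p = 0.0125, adjusted 0.05) and rho 0.829 (exact p = 0.0583, adjusted 0.233), with r = 0.673 without 2 libraries. In KPP r was −0.757 (exact p = 0.110, adjusted 0.146) and rho −0.600 (exact p = 0.242, adjusted 0.322), and it turned to 0.319 without 2 libraries, so the relation rests on those libraries. Neither relation with Ret passed the adjustment, and differences between the groups were not tested. The relations in KPP count KPP 1 and KPP 2 as separate samples, although the labels leave open whether they came from 1 animal or tumour. Of the KPP libraries these had the highest Ret. Both stayed in when KPP 3 and KPP 5, farthest from the median of Plk1, were left out. The mean of the alveolar type 2 list was 10.6, 10.7, 8.21, 9.98, 10.8 and 9.64 in KPP 1 to KPP 6. It was thus lowest in KPP 3, the KPP library with the lowest Plk1 and Ret. Whether Plk1 and Ret both follow the share of alveolar type 2-like RNA was not tested.

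A hypothesis that the groups differ in the copy number of chromosome 6 was tested on the median level of its 769 tested genes. The group means differed by 0.048 (log2, 95% interval −0.11 to 0.18; exact permutation p = 0.595, adjusted 0.853 over the chromosomes), and the interval reaches beyond 0.1 on both sides, so this explanation and its absence cannot be told apart. Chromosomes 14 and 18 had the smallest exact permutation p, 0.00866 each, adjusted 0.0866, with differences of −0.21 and 0.25.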
